A study of Mus musculus with 21 samples.

How the data were processed

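The deposited data were 21 scanner text files, 1 per array, and a pair of tables by the authors. Per the labels, total RNA was amplified and labelled with Cy3 for 1-colour Agilent arrays, from freshly isolated hepatocytes and CLiPs of female C57BL/6 mice. Per the file headers, all arrays had the same design, with 59305 non-control spots and 56605 probes, and Agilent Feature Extraction was version 11.5.1.1 for the fresh and P1 arrays and 10.7.3.1 for the late arrays, which came from another scanner. The processed signal in the scanner files is an intensity, background-subtracted and detrended, with no scaling between arrays, per the file headers. Both of the authors' deposited tables hold log2 values. The one with the fresh and P1 arrays was checked to equal the log2 processed signal minus the 75th percentile of each array, up to a constant, for 56605 probes. The other, with the fresh and late arrays (40786 probes), was centred on each probe's median as well. How the authors chose those probes is not given in the sources used here. The groups and replicate numbers came from the sample titles, and the passage, the time and the inducers from the labels. In the labels, a single fresh hepatocyte array carries a P1 passage, and it was kept with the fresh group as its title says. The titles number the replicates 1 to 3 in each group; the labels do not say whether these are separate cultures or animals, so the p-values measure the spread between these samples. Per the labels, late replicate 3 was passage 11 and the others passage 12.

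Control spots and spots flagged as outliers were left out, the log2 processed signals of the spots of a probe were averaged, and the 75th percentile over the probes of the array was subtracted. As alternatives, the arrays were quantile-normalized, or corrected by normexp (offset 50) on the mean signal and the median background of the spots, with the median signal for the late arrays, whose files give no mean. A gene, named as in the files, was represented by its probe with the highest mean over all 21 arrays. Of 37074 names, 11876 had several probes and 10314 were only an accession or probe name. The RefSeq accessions of 32994 probes were found in the reference table, which was built on GRCm38.p6 and used for names only, and 31459 of these had the same symbol. A gene was tested if its probe was well above background, by the flag in the scanner files, on all arrays of at least 1 group in the fit; 84 genes were left out for a flagged spot. A gene was called dim in a group if its probe was well above background on none of the arrays there. Its fold change was then given as a minimum, with the dim value on each array taken as at least the lowest signal of any probe well above background there. No spot was saturated. The 75th percentile signal was 291 to 332 on fresh, 466 to 789 on P1 and 881 to 1241 on late arrays, and 46.1% to 60.5% of probes were well above background.

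Group means were fitted with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, in one fit of the 12 fresh and P1 arrays, one of the 9 late arrays and, for the difference of the induction effects, one of all 21. P-values were adjusted by Benjamini-Hochberg over all tested genes. Changes with an adjusted p under 0.05 and at least 2-fold were called. The 34 gene lists, of which 569 of 575 entries were on the array, were written from general knowledge of these genes. All but the list of sex-linked genes, which served to check the samples, were tested with camera of limma at its preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with the correlation estimated from the data. At the preset correlation camera takes genes of a list as nearly independent, and no list passed with the estimated one in any comparison. Named genes were a core of 27 genes in every comparison, the 6 highest and 6 lowest called genes measured on all arrays of both groups and with no overlap between them, and up to 4 members of each list. Some genes are not reported here. Files were read with the R package data.table (version 1.17.8), the slide correlation used statmod 1.5.0, and figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.

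The groups, comparisons, lists, naming rule, thresholds and alternatives were set before the data were examined, except the fits within single slides, which were chosen after seeing the data. The fits were tested on simulated data with the same numbers of arrays, and the rates hold for such data only. Of 100 genes with a simulated log2 change of 2, 95 were called for P1 day 0 against fresh and 95 for P1 induction. Late induction gave 89, and the difference of the induction effects 84, with 12 of 22123 unchanged genes called. Among 442 called results of named genes with several probes, 59 had a probe of opposite sign and 84 a probe under 2-fold in the same direction.

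Slides were taken from the file headers. P1 day-0 and uninduced replicates 1 and 2 and induced replicate 1 lay on slide 4, the other P1 CLiP arrays on slide 5, the late arrays on slide 6 except 1 induced array on slide 7, and the fresh arrays on slides 1 to 3. Whether replicates with the same number belong together was checked by correlating their deviations from the group means. For P1 day 0 and uninduced cells the correlations were 0.396, 0.321 and 0.540, and for late uninduced and induced cells 0.495, 0.579 and 0.626, against at most 0.155 and -0.0356 between different numbers. The other late pairs with the same number had at least 0.228. The pairing thus comes from the data and not from the labels, and same-numbered P1 arrays of these groups also shared a slide. The replicate number entered as a block in an alternative fit. The 60-base probes of 4 key genes map, per the file headers on mm9, to chromosome 5 at 90905550 to 90905609 (Alb) and 90937781 to 90937840 (Afp), and to chromosome 11 at 100002392 to 100002451 (Krt19) and 117827480 to 117827539 (Socs3).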

Results

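Hepatocytes freshly isolated from female C57BL/6 mice were compared with the progenitor-like cells derived from them in culture (chemically induced liver progenitors, CLiPs). The CLiPs were profiled at passage 1 (P1) and at passages 11 to 12 (late), before hepatic induction (day 0) and after 8 days with or without oncostatin M and dexamethasone. Each of the 7 groups held 3 arrays, and log2 fold changes compare the first-named group with the second. A gene was said to have risen or fallen if its Benjamini-Hochberg adjusted p from limma was under 0.05 and its change at least 2-fold. For every gene so described, all 3 arrays of one group lay on the same side of all 3 of the other, except late Alb and late Afp where stated. Chance alone gives such a separation to 10% of genes. Genes that were dim in one group were given as at least so many fold, and a list median was followed by the bounded one, with dim genes set to that minimum, where it differed. The highest and lowest genes named in a comparison are those among genes well above background on all arrays of its groups, so dim genes may lie beyond them. A normexp or quantile median is that under normexp background correction or quantile normalization, given where a called list moved by over 1.5 times. Gene lists were tested with camera, and each called list was followed by the adjusted p from the same test with the correlation between genes estimated from the data (estimated-correlation adjusted p). The counts of list members were the same when p was adjusted over the list alone, unless a second count was given.

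Conversion of hepatocytes to P1 CLiPs lowered most of the hepatocyte program. Of genes measured in both groups, the lowest in P1 day-0 CLiPs against fresh hepatocytes were the major urinary protein genes Mup19 (log2 fold change -13.76), Mup1 (-12.85) and Mup5 (-12.11). They were followed by Slc27a5 (-12.00), which codes for a bile acid ligase, the cytochrome P450 gene Cyp2a5 (-11.98) and the apolipoprotein gene Apoc3 (-11.85). The drug metabolism gene Cyp3a11 (-10.57, adjusted p = 5.8e-10), G6pc of gluconeogenesis (-9.23) and the tyrosine aminotransferase gene Tat (-8.02) fell too. The albumin gene Alb (-1.45, SE 0.114), the thyroxine carrier gene Ttr (-3.19) and the hepatocyte regulator gene Hnf4a (-1.31) fell less. After quantile normalization Alb (-0.42) and Hnf4a (-0.78) were under 2-fold. Whether so bright a probe as that of Alb shows full changes, here or on induction, was not tested. Rising most among genes measured in both groups were the annexin genes Anxa3 (9.66) and Anxa2 (8.14), the fetal liver gene Afp (9.49), the RNA-binding protein gene Bicc1 (9.28), the biliary cytokine gene Spp1 (8.66) and the tubulin gene Tuba1a (8.51). Krt19, Krt7, Epcam and Cd24a, which mark bile duct and liver progenitor cells, were dim in fresh hepatocytes and at least 407-fold, 107-fold, 33.6-fold and 451-fold higher in CLiPs.

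Whole groups of hepatocyte genes fell. All 20 secreted protein genes fell (median -3.43, adjusted p = 2.2e-08, estimated-correlation adjusted p = 0.14), as did all 22 P450 and other phase I genes (median -8.87, bounded -8.14, adjusted p = 5.4e-10, estimated-correlation adjusted p = 0.078). Genes of the urea cycle and amino acid catabolism fell in 18 of 18 cases (median -9.49, bounded -9.14, adjusted p = 5.4e-10, estimated-correlation adjusted p = 0.078). Among these, Cyp2e1 was at least 10427-fold lower, Cyp2f2 at least 9499-fold, Agxt at least 4459-fold and the arginase gene Arg1 at least 3406-fold. All 14 genes of gluconeogenesis, glycogen and sugar metabolism fell (median -6.02, adjusted p = 2.6e-07, estimated-correlation adjusted p = 0.064), with Pck1 at least 3639-fold lower. In the list of complement and coagulation factors 24 of 25 fell (median -6.49, adjusted p = 5.4e-10, estimated-correlation adjusted p = 0.14). In that of bile acid synthesis and transport 16 of 17 fell (median -6.67, bounded -6.28, adjusted p = 1.7e-07, estimated-correlation adjusted p = 0.064), with the bile salt pump gene Abcb11 at least 3510.5-fold and Cyp7a1 at least 92.8-fold lower. Phase II conjugation enzyme genes fell in 16 of 17 cases (median -3.71, adjusted p = 1.8e-07, estimated-correlation adjusted p = 0.12). Of the 18 liver transcription factor genes 12 fell, 1 rose and 5 did not pass (median -2.33, adjusted p = 3.7e-04, estimated-correlation adjusted p = 0.078). Pericentral genes fell in 12 of 13 cases (median -4.94, adjusted p = 3.2e-06, estimated-correlation adjusted p = 0.068), with Cyp1a2 at least 165-fold lower. Periportal genes fell in 12 of 13 (median -8.25, adjusted p = 1.0e-05, estimated-correlation adjusted p = 0.064). Acute-phase genes fell in 22 of 28 cases and rose in 3 (median -3.80, bounded -3.65, adjusted p = 1.0e-05, estimated-correlation adjusted p = 0.14). Orm1 stood at -8.64 and the iron hormone gene Hamp at -8.98. Lipid genes fell too. In fatty acid oxidation 18 of 19 fell (median -3.17, bounded -2.92, adjusted p = 2.4e-08, estimated-correlation adjusted p = 0.078), where Fabp1 fell to a log2 fold change of -9.84. In fatty acid synthesis 12 of 14 fell (median -1.62, adjusted p = 9.7e-05, estimated-correlation adjusted p = 0.14), with Thrsp at -10.35 and Scd1 at -5.22. Cholesterol synthesis genes were not called as a list (6 of 20 fell, median -0.22, adjusted p = 0.24).

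Progenitor and biliary genes rose in 22 of 23 cases (median 6.08, bounded 4.95, adjusted p = 3.2e-09, estimated-correlation adjusted p = 0.064), and Sox9, a regulator of bile duct cells, rose with a log2 fold change of 2.35. Fetal liver and imprinted genes rose in 12 of 14 cases (median 5.36, bounded 5.01, adjusted p = 7.9e-05, estimated-correlation adjusted p = 0.064), with Igf2 at least 50.7-fold higher. Cell cycle genes rose in 29 of 30 cases (median 4.69, bounded 4.63, adjusted p = 6.7e-10, estimated-correlation adjusted p = 0.15), among them the proliferation marker gene Mki67 (6.05). Targets of p53 and cell cycle inhibitors rose in 12 of 18 (median 2.56, adjusted p = 1.5e-04, estimated-correlation adjusted p = 0.14), with Phlda3 at 7.64 and the inhibitor gene Cdkn2a at least 231-fold higher. Mesenchymal genes rose in 11 of 18 cases (median 2.39, bounded 2.03, normexp median 1.37, adjusted p = 0.034, estimated-correlation adjusted p = 0.55), among them the filament gene Vim (7.53). That list lost its call with the mean of all probes (median 1.42, adjusted p = 0.051) and when single arrays were left out (highest adjusted p 0.055). YAP/TEAD targets rose in 14 of 16 (median 3.58, adjusted p = 3.1e-05, estimated-correlation adjusted p = 0.14), with Ankrd1 at least 866-fold higher. The oncostatin M receptor gene Osmr rose (4.88, adjusted p = 1.1e-08), while its target gene Socs3 (-0.78) and the glucocorticoid target gene Fkbp5 (0.21) did not pass.

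Markers of other liver cells moved with these groups. Endothelial genes fell in 10 of 12 cases (median -3.88, bounded -2.92, normexp median -2.46, adjusted p = 3.1e-05, estimated-correlation adjusted p = 0.14) and Kupffer cell and macrophage genes in 12 of 14 (median -3.92, bounded -2.74, normexp median -2.29, adjusted p = 3.7e-04, estimated-correlation adjusted p = 0.34). The vascular receptor gene Kdr was at least 32.4-fold, the Kupffer cell lectin gene Clec4f at least 20.8-fold and Cd5l at least 69.1-fold lower in CLiPs. Another probe of Kdr gave -0.21. The 4 tested erythroid genes fell (median -1.27, adjusted p = 0.037, estimated-correlation adjusted p = 0.27). Interferon-stimulated genes fell in 11 of 16 cases (median -2.59, adjusted p = 0.0076, estimated-correlation adjusted p = 0.38). Stellate cell genes were mixed, with 4 of 11 higher and 4 lower (median -0.02, adjusted p = 0.68). Reln rose (3.73, other probes down to -0.59) and Cxcl12 fell (-8.00). The mesothelial marker gene Msln was at least 162-fold higher. The lists of TGF-beta targets (6 up and 3 down of 13, median 0.47, adjusted p = 0.26) and NRF2 targets (5 up and 2 down of 13, median 0.34, adjusted p = 0.46) were not called. Neither were those of glucocorticoid-responsive genes (2 up and 8 down of 18, median -0.69, adjusted p = 0.17) and the unfolded protein response (1 up and 5 down of 15, median -0.76, adjusted p = 0.44). Wnt feedback targets (2 up, 3 or, adjusted over the list alone, 2 down of 10, median 0.08, adjusted p = 0.81) and immediate early and heat shock genes (5 up and 7 down of 18, median -0.59, adjusted p = 0.69) were not called either. In both, median, mean and test direction differed in sign. The 3 lymphocyte genes gave an adjusted p of 0.81. Over all genes 5236 of 20619 rose and 5201 fell. The lists called up were 6 and those called down 17, and with an estimated correlation 0 lists passed (lowest adjusted p 0.064). Fresh hepatocytes and CLiPs shared no slide, and with the slide as a random block 5191 genes rose and 5197 fell.

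**Figure D1:**
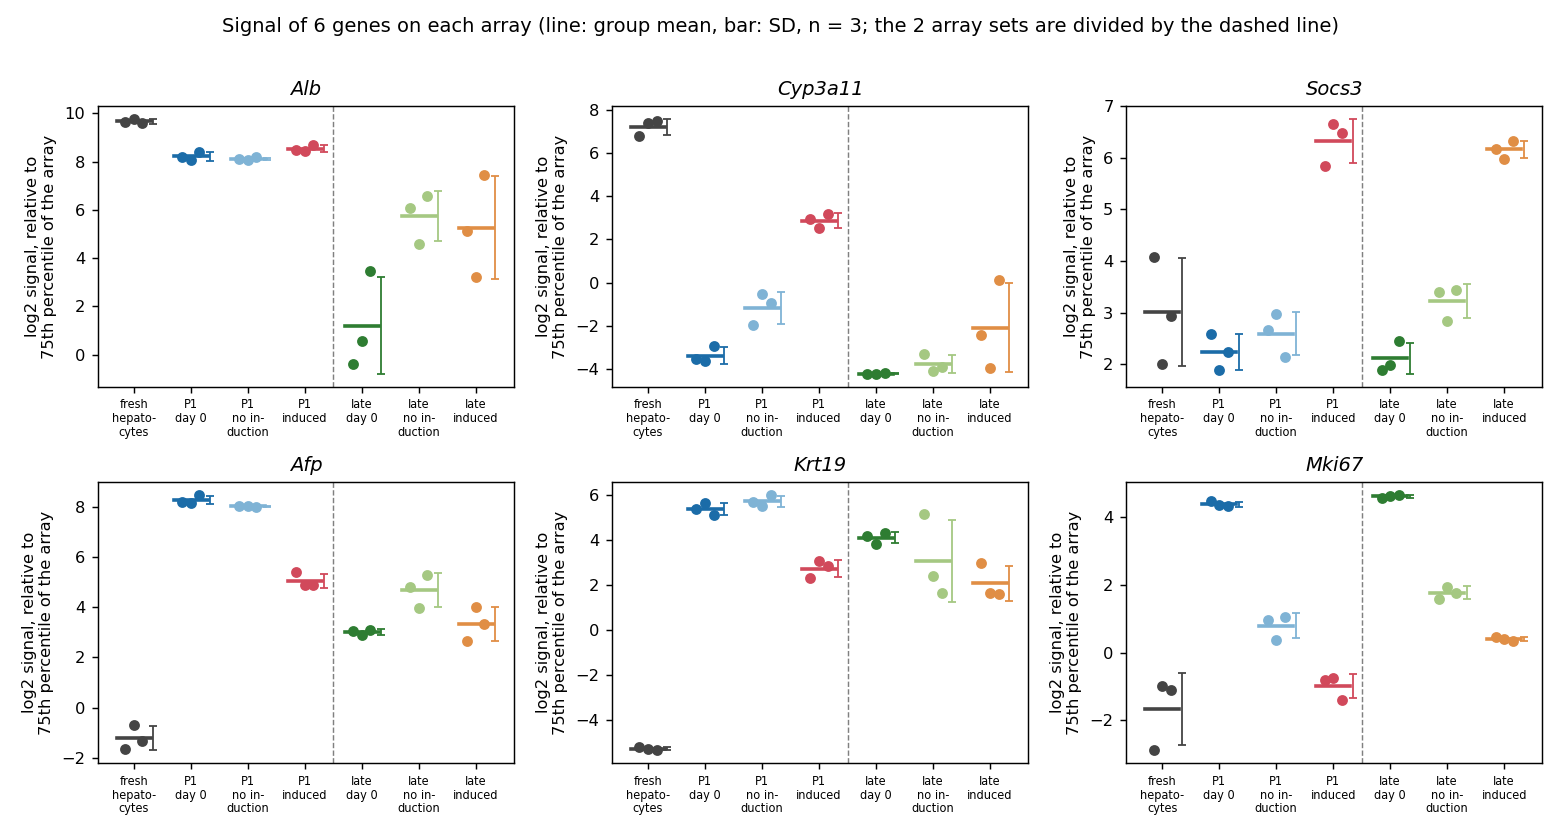
Log2 intensity of Alb, Cyp3a11, Socs3, Afp, Krt19 and Mki67 on each of the 21 arrays, relative to the 75th percentile of the array, with the mean and SD of each group. Alb on the late day-0 arrays ranged from -0.40 to 3.46.

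Over 8 days without induction, cell cycle genes fell in P1 CLiPs. All 30 of them passed (median -3.29, adjusted p = 3.5e-23, estimated-correlation adjusted p = 0.28). The lowest named genes were Hist1h1b (-3.87), which codes for a linker histone, the separase gene Espl1 (-3.81), the survivin gene Birc5 (-3.80) and the mitotic kinase gene Pbk (-3.79), with Mki67 at -3.60. Bub1 (-3.97) and Depdc1b (-3.90) fell furthest by their brightest probe, but another probe of each gave -0.11 and -0.13. Cholesterol synthesis genes fell in 17 of 20 cases (median -1.64, adjusted p = 1.2e-11, estimated-correlation adjusted p = 0.34), among them Idi1 (-2.40), Lss (-2.01, another probe -0.94) and the feedback gene Insig1 (-1.92). The highest genes were S100b (4.72), which codes for a calcium-binding protein, the surfactant protein gene Sftpd (4.54), the interferon-inducible GTPase gene Tgtp2 (4.22), the stress gene Nupr1 (4.20, another probe 0.24), the channel subunit gene Kcne3 (4.09) and the protease inhibitor gene Mug1 (4.03).

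Part of the liver program rose without induction. Acute-phase genes rose in 15 of 28 cases and fell in 1 (median 1.13, adjusted p = 4.5e-08, estimated-correlation adjusted p = 0.28), with Serpina3n (3.92), Itih3 (3.16), Saa2 (3.11) and Lbp (2.96) among them. Complement and coagulation genes rose in 9 of 25 cases (median 0.78, bounded 0.68, normexp median 0.51, adjusted p = 6.1e-05, estimated-correlation adjusted p = 0.75). Fatty acid oxidation genes rose in 6 of 19 (median 0.57, adjusted p = 2.0e-06, estimated-correlation adjusted p = 0.28), with Fabp1 at 2.87. Progenitor and biliary genes rose in 6 of 23 (median 0.47, adjusted p = 0.013, estimated-correlation adjusted p = 0.46). Cyp3a11 (2.22) and G6pc (2.44) rose. Sox9 (1.07) and Cdkn2a (1.05) passed by a small margin and lost the call when single arrays were left out (lowest values 0.93 and 0.94). Fkbp5 fell (-1.19; its probes ranged up to -0.11). Alb (-0.10), Afp (-0.25), Krt19 (0.35), Socs3 (0.36) and Hnf4a (-0.76) did not pass. Fatty acid synthesis genes (3 of 14 lower, median -0.53, adjusted p = 0.0064, estimated-correlation adjusted p = 0.50) were called down as a list, with Elovl6 at -2.37. So were NRF2 targets (1 of 13 lower, adjusted over the list alone 1 higher and 1 lower, median -0.58, bounded -0.48, adjusted p = 0.0064, estimated-correlation adjusted p = 0.28), with Gsta4 at -1.97. P450 and other phase I genes rose in 4 of 22 cases (median 0.61, bounded 0.09, adjusted p = 0.051). In the lists of phase II enzymes, mesenchymal genes, interferon-stimulated genes and Kupffer cell genes, none of them called, median, mean and test direction differed in sign.

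In all, 1295 genes rose and 1002 fell over the 8 days without induction, and under normexp 752 and 805. With the slide as a block the counts were 1352 and 1030. Within slide 4 they were 1134 and 946, and within slide 5, with 1 array per group, 584 and 501. The cell cycle median was -3.29 with the block, -3.47 within slide 4 and -2.96 within slide 5. In the same order the cholesterol median was -1.64, -1.72 and -1.47, and the acute-phase median 1.13, 1.14 and 1.25. Within a slide each P1 group held 1 or 2 arrays and the spread came from all groups of the fit, so here and below such values show the size of a change and are no separate test. The call of Sdf2l1, an endoplasmic reticulum gene, was lost with the replicate number as a block (-1.04, adjusted p = 0.043, with the block 0.058).

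Induction with oncostatin M and dexamethasone raised liver genes and lowered progenitor genes in P1 CLiPs. The highest genes against 8 days without induction were the protease inhibitor genes A2m (8.69), Serpina3k (8.34) and Serpina3j (7.58), the acute-phase genes Saa2 (8.41) and Orm3 (8.24), and Bhmt (7.73), which codes for an enzyme of methionine metabolism. Known target genes of the inducers, which were always given together, rose, namely Socs3 (3.73, adjusted p = 7.3e-05) and Osmr (1.66) of the oncostatin M pathway, and Fkbp5 (2.21, other probes down to 0.54) and Tat (3.00) of the glucocorticoid pathway. Cyp3a11 rose (4.03, adjusted p = 7.1e-06), as did G6pc (3.19), the urea cycle gene Cps1 (3.42), Ttr (1.62) and Hnf4a (1.31). Hnf4a was under 2-fold after quantile normalization (0.95). Alb did not pass (0.42, adjusted p = 0.012). The lowest genes measured in both groups were the chemokine gene Cxcl5 (-6.08), Gxylt2 (-5.78), the creatine kinase gene Ckb (-4.98), the matrix gene Thbs1 (-4.80) and the transporter gene Slc4a11 (-4.69), with Flrt3 at -5.87 by its brightest probe and 0.48 by another.

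Acute-phase genes rose in 25 of 28 cases (median 3.13, adjusted p = 1.6e-15, estimated-correlation adjusted p = 0.10). Complement and coagulation genes rose in 23 of 25 (median 3.85, adjusted p = 1.0e-14, estimated-correlation adjusted p = 0.10), among them the clotting factor gene F10 (6.56) and the lectin gene Mbl1, at least 47.1-fold higher. Glucocorticoid-responsive genes rose in 10 of 18 (median 1.19, adjusted p = 0.0021, estimated-correlation adjusted p = 0.10). Secreted protein genes rose in 13, or 14 adjusted over the list alone, of 20 cases (median 1.95, adjusted p = 4.6e-10, estimated-correlation adjusted p = 0.11). P450 and other phase I genes rose in 13 of 22 (median 1.61, adjusted p = 3.7e-07, estimated-correlation adjusted p = 0.11), with Cyp2f2 at least 17.0-fold higher. Phase II genes rose in 13 of 17 with 2 lower (median 1.43, bounded 1.29, adjusted p = 2.3e-05, estimated-correlation adjusted p = 0.14). Urea cycle and amino acid genes rose in 14 of 18 (median 2.47, bounded 2.46, adjusted p = 2.1e-08, estimated-correlation adjusted p = 0.10), with Arg1 at least 71.0-fold higher. Gluconeogenesis genes rose in 11 of 14 (median 2.79, adjusted p = 1.1e-06, estimated-correlation adjusted p = 0.10), with Fbp1 at 5.99 and the pyruvate carboxylase gene Pcx at 4.04. Bile acid genes rose in 8 of 17 (median 1.04, bounded 0.82, adjusted p = 1.6e-04, estimated-correlation adjusted p = 0.10), with Abcb11 at least 68.3-fold higher. Liver transcription factor genes rose in 10 of 18 (median 1.10, adjusted p = 8.7e-04, estimated-correlation adjusted p = 0.10) and periportal genes in 7 of 13 (median 1.35, bounded 1.23, adjusted p = 0.0016, estimated-correlation adjusted p = 0.10). Pericentral genes were not called as a list (4 of 13 higher, median 0.72, bounded 0.23, adjusted p = 0.23). Cyp1a2 and Cyp7a1 were not well above background in either group.

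Lipid and stress lists moved as well. Fatty acid synthesis genes rose in 8 of 14 cases (median 1.33, adjusted p = 8.8e-06, estimated-correlation adjusted p = 0.10), with Thrsp at 6.61 and Scd1 at 4.99. Fatty acid oxidation genes rose in 6, or 7 adjusted over the list alone, of 19 (median 0.81, adjusted p = 2.5e-04, estimated-correlation adjusted p = 0.14). Cholesterol synthesis genes rose in 15 of 20 cases (median 1.32, adjusted p = 1.7e-07, estimated-correlation adjusted p = 0.18), among them Insig1 (2.06), Lss (2.05) and the squalene epoxidase gene Sqle (2.01, another probe 0.78). The unfolded protein response rose in 11 of 15 (median 1.21, adjusted p = 5.1e-05, estimated-correlation adjusted p = 0.10), with the kinase-like gene Trib3 at 3.17. NRF2 targets (5 up and 4 down of 13, median 0.25, adjusted p = 0.49) and immediate early and heat shock genes (1 up and 2 down of 18, median -0.24, adjusted p = 0.38) were not called.

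Progenitor and biliary genes fell in 15 of 23 cases and rose in 2 (median -2.0, adjusted p = 7.6e-08, estimated-correlation adjusted p = 0.10). Afp fell with a log2 fold change of -2.97, Krt19 with -3.01, Krt7 with -2.37, Epcam with -2.15 and the stem cell marker gene Prom1 with -3.36. Cd44 fell (-2.25), and Sox9 (-0.30) and Vim (-0.45) did not pass. Fetal liver and imprinted genes fell in 7 of 14 cases (median -1.10, bounded -0.56, normexp median -0.63, adjusted p = 0.011, estimated-correlation adjusted p = 0.10), with Meg3 at -3.88 and Dlk1 at least 129-fold lower. YAP/TEAD targets fell in 12 of 16 (median -1.57, adjusted p = 1.1e-07, estimated-correlation adjusted p = 0.10), with Cyr61 at -4.00 and Ankrd1 at -2.97. Wnt feedback targets fell in 5 of 10 (median -0.99, bounded -0.77, normexp median -0.39, adjusted p = 0.026, estimated-correlation adjusted p = 0.11), with Sp5 at -3.19. TGF-beta targets fell in 5, or 6 adjusted over the list alone, of 13 (median -1.10, normexp median -0.57, adjusted p = 0.044, estimated-correlation adjusted p = 0.14). Cell cycle genes fell in 21 of 30 cases (median -1.32, bounded -1.20, adjusted p = 7.3e-10, estimated-correlation adjusted p = 0.14), with Mki67 at -1.78 (-1.47 and -2.12 within the slides). Targets of p53 and cell cycle inhibitors fell in 9 of 18 (median -1.03, adjusted p = 9.0e-05, estimated-correlation adjusted p = 0.12), with Cdkn2a at -2.56, while the p53 target gene Cdkn1a stood at 0.06 and did not pass. Interferon-stimulated genes fell in 5 of 16 (median -0.67, adjusted p = 0.033, estimated-correlation adjusted p = 0.52). The TGF-beta and interferon lists lost their calls with the slide as a block (adjusted p = 0.068 and 0.13), under quantile normalization (0.095 and 0.096) and when single arrays were left out (highest adjusted p 0.076 and 0.065; TGF-beta median up to -0.56). The Wnt list lost its call under quantile normalization (0.053). Of the lists for other cells none was called. Endothelial genes rose in 1 of 12 cases (median 0.40, bounded 0.08, adjusted p = 0.11). Kupffer cell genes rose in 1 and fell in 1 of 14 (median 0.35, bounded 0.00, adjusted p = 0.85), and stellate cell genes rose in 2, with the chemokine gene Cxcl12 at 6.12, and fell in 4 of 11 (median -0.32, adjusted p = 0.33). Mesenchymal genes were not called (3 up and 3 down of 18, median 0.34, adjusted p = 0.89), and their median differed in sign from the test.

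Induction at P1 changed 1997 genes upward and 1860 downward, while 15 lists were called up and 8 down. Under normexp the counts were 1630 and 1169. The counts were 2078 and 1903 with the slide as a block. Slide 4 held 1 induced and slide 5 held 1 uninduced array. The counts were 1820 and 1483 within slide 4, and 1809 and 1499 within slide 5. All 23 called lists kept the sign of their median with the block, and 21 stayed called. Medians with the block, within slide 4 and within slide 5 were 3.27, 3.01 and 3.39 for acute-phase genes, 1.65, 1.91 and 1.38 for P450 and other phase I genes. They were -1.51, -1.65 and -1.43 for YAP/TEAD targets and 1.29, 1.45 and 1.12 for cholesterol synthesis.

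**Figure D2:**
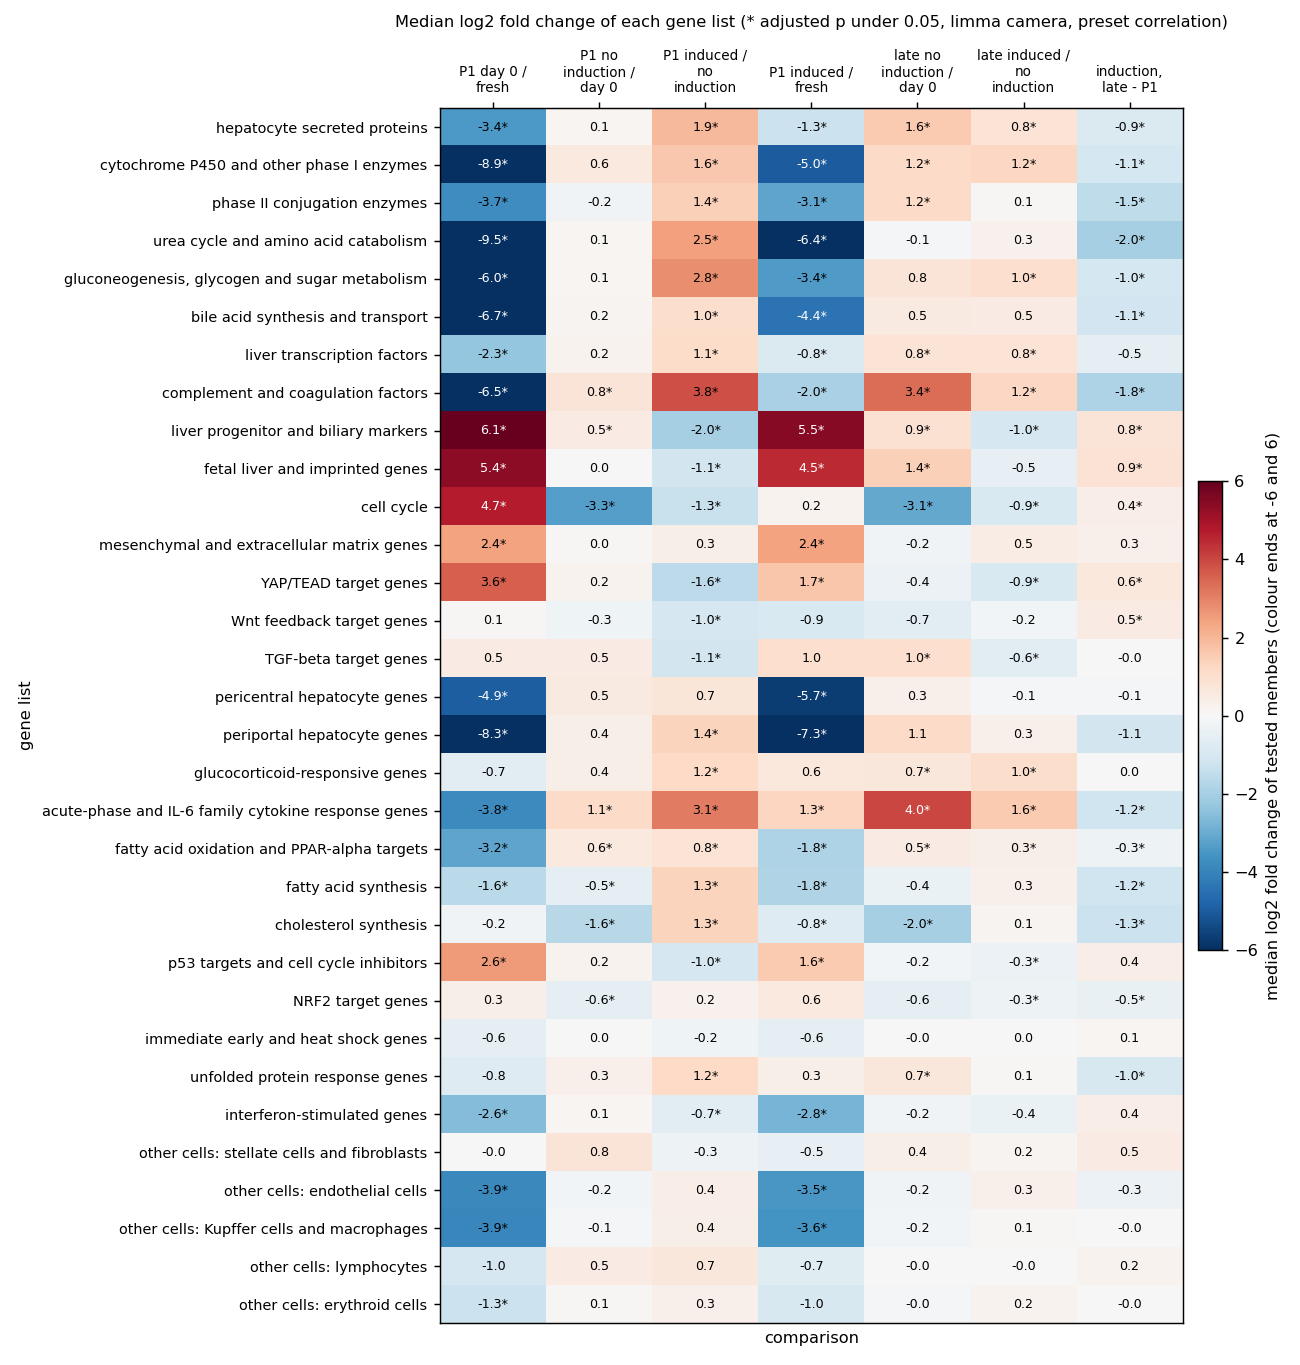
Median log2 fold change of each gene list in each comparison, with a star where the adjusted p of the list was under 0.05. In the induction comparison at P1 the median was 3.13 for acute-phase genes and -1.57 for YAP/TEAD targets.

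Against P1 day-0 CLiPs, induced P1 CLiPs combined the 8-day and the induction changes. The acute-phase genes Saa2 (11.51), Serpina3n (10.15), Orm2 (10.05), Orm1 (9.34) and Saa1 (9.19) and the protease inhibitor gene Serpina3m (9.94) were highest, and 27 of 28 acute-phase genes rose (median 4.33, bounded 4.28, adjusted p = 3.6e-16, estimated-correlation adjusted p = 0.11). The lowest were Slc4a11 (-6.75), the chemokine genes Cxcl5 (-6.51) and Ccl20 (-6.42), the tetraspanin gene Tspan8 (-6.38), the steroid enzyme gene Akr1c18 (-6.26) and Ckb (-6.05). All 30 cell cycle genes fell (median -4.59, bounded -4.45, adjusted p = 2.2e-20, estimated-correlation adjusted p = 0.11), with Mki67 at -5.37. Cyp3a11 rose (6.24), as did P450 and other phase I genes in 17 of 22 cases (median 2.25, adjusted p = 5.6e-08, estimated-correlation adjusted p = 0.12). Complement and coagulation genes rose in 22 of 25 (median 4.56, bounded 4.29, adjusted p = 1.2e-14, estimated-correlation adjusted p = 0.12). Vim fell (-1.08; -0.91 within slide 4 and -1.24 within slide 5). Fkbp5 (1.01, another probe 0.42) lost its call when single arrays were left out (lowest value 0.91). Alb (0.32), Ttr (0.79) and Hnf4a (0.55) did not pass. Cholesterol synthesis genes were not called (1 up and 1 down of 20, median -0.22, adjusted p = 0.19). Fatty acid synthesis genes rose in 5 of 14 cases (median 0.59, adjusted p = 0.044, estimated-correlation adjusted p = 0.40), and the list lost its call with the slide as a block (0.060) and when single arrays were left out (highest adjusted p 0.080). The mesenchymal, TGF-beta, NRF2 and stellate lists, none of them called, had a median, mean and test that differed in sign. In total 2569 genes rose and 2167 fell. These counts were 2637 and 2193 with the slide as a block, 2237 and 1896 within slide 4, and 2280 and 1872 within slide 5. The acute-phase median was 4.48, 4.30 and 4.51 in these, and the cell cycle median -4.59, -4.37 and -4.50.

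Compared with fresh hepatocytes, metabolic genes stayed low in induced P1 CLiPs. The lowest were the carboxylesterase gene Ces3a (-11.80), the P450 genes Cyp2a4 (-11.03), Cyp2c50 (-10.50) and Cyp2c37 (-10.31), Mup2 (-10.50) and Hpd (-10.33), an enzyme gene of tyrosine breakdown. Alb fell with a log2 fold change of -1.13 (SE 0.114; -0.40 after quantile normalization, which was under 2-fold), Ttr with -2.40, Cyp3a11 with -4.33 and Cps1 with -5.38. All 22 P450 and other phase I genes fell (median -5.01, adjusted p = 2.4e-09, estimated-correlation adjusted p = 0.094), and so did all 18 urea cycle and amino acid genes (median -6.41, adjusted p = 1.6e-10, estimated-correlation adjusted p = 0.082). Gluconeogenesis genes fell in 13 of 14 cases (median -3.39, adjusted p = 5.9e-06, estimated-correlation adjusted p = 0.075). Secreted protein genes fell in 12 of 20 cases and 8 did not pass (median -1.27, quantile median -0.68, adjusted p = 6.0e-06, estimated-correlation adjusted p = 0.24). The highest genes were Spp1 (9.62), Bicc1 (8.79), the protease inhibitor gene Spink1 (8.59), the asparagine synthetase gene Asns (8.52), the lipopolysaccharide receptor gene Cd14 (8.17) and Tmsb10 (8.15, another probe 0.38). Afp (6.26), Socs3 (3.32) and Osmr (7.27) rose, and Krt19 was at least 64.8-fold higher, while Mki67 (0.68), Hnf4a (-0.76) and Prom1 (-0.28) did not pass.

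Acute-phase genes lay above the fresh level in 15 of 28 cases and below it in 4 (median 1.29, adjusted p = 0.018, estimated-correlation adjusted p = 0.40). Complement and coagulation genes fell in 16 of 25 cases and rose in 1 (median -1.97, adjusted p = 5.4e-05, estimated-correlation adjusted p = 0.32). Progenitor and biliary genes rose in 19 and fell in 1 of 23 (median 5.48, bounded 3.97, normexp median 3.32, adjusted p = 8.0e-08, estimated-correlation adjusted p = 0.075). Interferon-stimulated genes fell in 15 of 16 cases (median -2.78, adjusted p = 3.7e-05, estimated-correlation adjusted p = 0.23). Endothelial genes fell in 10 of 12 (median -3.49, bounded -2.33, normexp median -1.96, adjusted p = 1.4e-05, estimated-correlation adjusted p = 0.16) and Kupffer cell genes in 11 of 14 (median -3.60, bounded -2.33, normexp median -1.96, adjusted p = 2.4e-04, estimated-correlation adjusted p = 0.32). Immediate early and lymphocyte genes, not called, had a median, mean and test that differed in sign. The counts were 4192 genes higher and 3874 lower, and with the slide as a random block 4115 and 3772. Under normexp they were 2576 and 3137.

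Induction returned part of what conversion had changed, as seen in pairs of comparisons that share no array. Of 5201 genes that fell on conversion, 1295 rose with induction at P1 (24.9%, 504 by chance), among them Cyp3a11, G6pc, Cps1 and Tat. Another 122 fell further (469 by chance). Of 5236 genes that rose on conversion, 1422 fell with induction (27.2%, 472 by chance), Afp, Krt19 and Prom1 among them. Genes already dim in P1 CLiPs could rise but hardly fall, so none of these chance counts is a fair expectation. Across all 20619 genes the fold changes of conversion and induction correlated with r = -0.58 (Spearman rho -0.56), where genes are not independent replicates. The mean correlation of each array with the fresh hepatocyte mean was 0.720 (SD 0.00708) at day 0, 0.724 (SD 0.00354) without and 0.822 (SD 0.00906) with induction. The difference between the last pair of groups was 0.0979 (0.0412 without a filter on dim probes), and its exact permutation p of 0.1 (two-sided) is the smallest possible with 3 arrays per group.

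**Figure D3:**
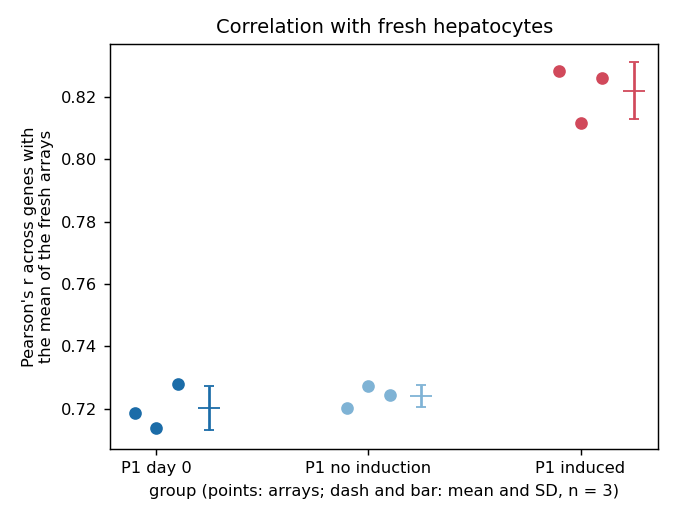
Correlation of each P1 array with the mean of the fresh hepatocyte arrays over all tested genes, with group means of 0.720, 0.724 and 0.822.

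Late CLiPs still responded to induction. Among the highest genes with induction against 8 days without it were Serpina3n (8.24), the decoy receptor gene Il1r2 (6.22), Glod5 (5.57), Tmem45a (5.08) and Itih3 (4.96). Socs3 rose (2.93, adjusted p = 1.8e-04). Osmr passed by a small margin (1.04, another probe 0.72) and lost the call when single arrays were left out (lowest value 0.95). The glucocorticoid targets Fkbp5 (2.19), Zbtb16 (2.29) and the kinase gene Pdk4 (2.07) rose. The acute-phase gene Lrg1 (4.15), the P450 gene Cyp2a5 (4.35), the regulator gene Cebpa (2.01) and the imprinted growth factor gene Igf2 (3.00) rose as well. The lowest genes were the chemokine genes Ccl20 (-4.52) and Ccl7 (-4.34), the guidance factor gene Sema3c (-4.47), Slc4a11 (-4.02), Thbs1 (-3.87) and the protease inhibitor gene Timp3 (-3.78). Afp passed (-1.35, adjusted p = 0.048) without a clear separation of the arrays, and did not pass with the replicate number as a block (adjusted p = 0.062), with the slide as a block (0.083) or when single arrays were left out.

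Alb (-0.49), Hnf4a (0.44), Krt19 (-0.99), Cyp3a11 (1.69), Tat (0.20) and Cdkn2a (-0.65) did not pass. G6pc stood at 3.18 (adjusted p = 0.070) and passed with the replicate number as a block (0.011), and so did Krt7 (-1.50, 0.043), Epcam (-1.72, 0.039) and Prom1 (-1.04, 0.037). Cyp1a2, Cyp7a1 and Col1a1 were not well above background in either group.

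Glucocorticoid-responsive genes rose in 8, or 9 adjusted over the list alone, of 17 cases (median 1.03, adjusted p = 2.0e-07, estimated-correlation adjusted p = 0.074). Acute-phase genes rose in 9, or 12 adjusted over the list alone, of 27 (median 1.55, adjusted p = 5.3e-04, estimated-correlation adjusted p = 0.51). Complement and coagulation genes rose in 4 of 17 cases (median 1.22, adjusted p = 0.022, estimated-correlation adjusted p = 0.74), and P450 and other phase I genes in 4 of 14 (median 1.23, adjusted p = 0.014, estimated-correlation adjusted p = 0.45). Liver transcription factor genes rose in 4 of 17 (median 0.80, adjusted p = 0.012, estimated-correlation adjusted p = 0.46). Gluconeogenesis genes rose in 3, or 4 adjusted over the list alone, of 11 (median 0.99, adjusted p = 0.040, estimated-correlation adjusted p = 0.74). Secreted protein genes rose in 2, or 0 adjusted over the list alone, of 17 (median 0.82, adjusted p = 0.040, estimated-correlation adjusted p = 0.74). Fatty acid oxidation genes were called up as a list (median 0.33, adjusted p = 0.012, estimated-correlation adjusted p = 0.51) with no member passing. Urea cycle genes (0 of 11 higher, median 0.26, adjusted p = 0.23), bile acid genes (0 of 8, median 0.49, adjusted p = 0.64) and phase II genes (1 up and 1 down of 14, median 0.06, adjusted p = 1.0) were not called. Unfolded protein response genes (0 of 15, median 0.07, adjusted p = 0.40) and periportal genes (1 of 9, median 0.29, adjusted p = 0.29) were not called either. No cholesterol synthesis gene passed (0 of 20 in limma), and the list was not called (median 0.15, adjusted p = 0.89).

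Cell cycle genes fell in 14 of 30 cases (median -0.89, adjusted p = 1.3e-15, estimated-correlation adjusted p = 0.42), with Mki67 at -1.36. YAP/TEAD targets fell in 7 of 15 (median -0.90, adjusted p = 7.6e-10, estimated-correlation adjusted p = 0.15), with Cyr61 at -3.16 and Ankrd1 at -2.28. TGF-beta targets fell in 5 of 12 (median -0.64, normexp median -0.39, adjusted p = 0.0049, estimated-correlation adjusted p = 0.42). Targets of p53 and cell cycle inhibitors fell in 3 of 18 (median -0.34, adjusted p = 2.6e-04, estimated-correlation adjusted p = 0.42), with Cdkn2b at -1.41 and Gdf15 at -2.18. NRF2 targets fell in 3 of 12 (median -0.33, adjusted p = 0.026, estimated-correlation adjusted p = 0.51), a call lost when single arrays were left out (highest adjusted p 0.051). Progenitor and biliary genes fell in 5, or 7 adjusted over the list alone, of 24 (median -1.02, adjusted p = 9.9e-04, estimated-correlation adjusted p = 0.53; median up to -0.50 without single arrays), with Cd44 at -1.30. The call of Slc7a11 (-1.24, adjusted p = 0.038; another probe 0.62), an NRF2 target, was lost with the replicate number as a block (adjusted p = 0.052). Interferon-stimulated genes (1, or 0 adjusted over the list alone, of 16 lower, median -0.42, adjusted p = 0.097) were called with the replicate number as a block only (adjusted p = 0.043). The 3 tested mesothelial genes (1 lower, median -0.38, adjusted p = 0.29) were not called. The pericentral, cholesterol, immediate early, endothelial, Kupffer cell and lymphocyte lists, none of them called, had a median, mean and test that differed in sign.

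The late induction counts were 626 genes higher and 652 lower of 21313, and under normexp 502 and 392. With the slide as a block, which leaves out the single late array on slide 7, they were 638 and 642. All 14 called lists kept the sign of their median then, but 8 stayed called: the lists of secreted proteins, P450 genes, gluconeogenesis, liver transcription factors, complement factors and fatty acid oxidation did not. The medians with the block were 1.13 for acute-phase genes, 1.11 for glucocorticoid-responsive genes, -0.88 for cell cycle genes, -0.88 for YAP/TEAD targets and 0.76 for P450 and other phase I genes. They were 0.64 for complement and coagulation, 0.41 for secreted protein, 0.59 for gluconeogenesis and 0.42 for liver transcription factor genes. The array on slide 7, induced replicate 3, lay above the other induced arrays in Cyp3a11 (0.12 against -2.42 and -3.92) and Abcb11 (-0.47 against -3.63 and -5.79). Without single arrays the complement median ranged from 0.64 to 2.31.

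Over 8 days, late CLiPs raised some liver genes with and without induction, but not the urea cycle list (adjusted p = 0.65 and 0.97). With induction the highest genes against late day 0 included the fibrinogen gene Fgg (10.45), Lrg1 (9.84), the complement genes C4b (8.80) and Serping1 (8.43) and Anxa8 (8.29). Without induction they included C4b (8.49), the lipid droplet gene Cidea (6.41), Saa3 (6.29), Agt (5.95) and Anxa8 (5.73). The lowest with induction were Ccl20 (-7.17), the interleukin gene Il11 (-6.58), Fam64a (-5.54), Espl1 (-5.40), the AP-1 gene Fosl1 (-5.39) and the mitotic motor gene Kif23 (-5.39, another probe -0.17). Without induction they were the granzyme gene Gzme (-4.28), Fosl1 (-4.26), the channel gene Trpa1 (-4.23), Il11 (-4.10) and Aunip (-3.98). Socs3 rose in both (with induction 4.05, without 1.12), as did Ttr (3.32 and 2.50), Sox9 (2.15 and 1.97) and Osmr (3.41 and 2.37). Mki67 fell in both (-4.22 and -2.86). Fkbp5 rose with induction (1.62) and did not pass without (-0.57). Afp stood at 0.33 with and rose without induction (1.67).

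Alb rose with a log2 fold change of 4.06 with and 4.55 without induction (SE 1.26 for each), but the 3 late day-0 arrays lay far apart in Alb (-0.40, 0.56 and 3.46 log2 units from the 75th percentile). The arrays overlapped in Alb between induced and day-0 cells, and the call was lost when single arrays were left out (highest adjusted p 0.086 with and 0.067 without induction) and, with induction, with the slide as a block (0.071). Within pairs of the same replicate number Alb was higher by 5.53, 2.66 and 3.99 with and by 6.49, 4.04 and 3.14 without induction. Acute-phase genes rose in 25 of 27 cases with induction (median 4.64, adjusted p = 3.9e-09, estimated-correlation adjusted p = 0.28) and in 23 without (median 4.02, bounded 3.01, normexp median 2.35, adjusted p = 3.5e-09, estimated-correlation adjusted p = 0.38). Complement and coagulation genes rose in 15 of 17 cases with induction (median 4.78, bounded 3.78, adjusted p = 9.6e-05, estimated-correlation adjusted p = 0.52). Without it they rose in 10, or 13 adjusted over the list alone (median 3.36, bounded 2.65, normexp median 2.14, adjusted p = 1.8e-04, estimated-correlation adjusted p = 0.51). Secreted protein genes rose in 12, or 13 adjusted over the list alone, of 17 cases with induction (median 3.32, adjusted p = 7.7e-04, estimated-correlation adjusted p = 0.54) and in 7 without (median 1.56, adjusted p = 0.0033, estimated-correlation adjusted p = 0.60). Cholesterol synthesis genes fell in 17 of 20 cases with induction (median -1.92, adjusted p = 1.7e-10, estimated-correlation adjusted p = 0.28) and in 18 without (median -1.98, adjusted p = 2.9e-12, estimated-correlation adjusted p = 0.38), with Idi1 at -3.18 and -2.94. All 30 cell cycle genes fell, both with (median -3.78, adjusted p = 7.9e-22, estimated-correlation adjusted p = 0.28) and without induction (median -3.06, adjusted p = 4.9e-22, estimated-correlation adjusted p = 0.38). YAP/TEAD targets fell in 9 of 15 with induction (median -1.74, adjusted p = 1.4e-04, estimated-correlation adjusted p = 0.28) and were not called without (median -0.37, adjusted p = 0.20).

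The counts were 2375 genes higher and 2046 lower with induction and 1745 and 1355 without, where they were 1129 and 1053 under normexp. With the slide as a block they were 2396 and 2037, and 1786 and 1376, and the acute-phase medians 4.66 and 4.02. With the replicate number as a block, Krt19 passed in the comparison with induction (-2.03, adjusted p = 0.030). In that without induction G6pc (2.53, 0.011), Krt7 (2.06, 0.0073), Epcam (1.75, 0.020) and Msln (-1.84, 0.0088) passed. The unfolded protein response list (median 0.69, adjusted p = 0.045, estimated-correlation adjusted p = 0.61) lost its call (0.073), as it did when single arrays were left out (highest 0.064). Lists whose median, mean and test differed in sign, none of them called, were with induction progenitor, TGF-beta, pericentral, fatty acid synthesis, endothelial and Kupffer cell genes, and without it urea cycle, immediate early, Kupffer cell and lymphocyte genes.

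Against uninduced cells of the same passage, the inducers acted less on liver genes in late than in P1 CLiPs. This was tested by the difference between the induction effects (late minus P1). The lowest genes were the serum amyloid genes Saa1 (-8.76; late -1.23, P1 7.52), Saa2 (-6.41) and Saa3 (-5.44), the carboxypeptidase gene Cpb2 (-5.99), the cysteine synthesis gene Cth (-5.59) and Slc27a5 (-5.23). Tat responded at P1 only (-2.79; late 0.20, P1 3.00), and Cps1 differed (-1.95), though it was dim on some late arrays. The highest genes were Glod5 (5.89; late 5.57, P1 -0.32), the imprinted genes Meg3 (5.13) and Igf2 (4.25), the RNA sensor gene Tlr3 (4.42), Gxylt2 (3.77) and Tspan8 (3.76). The effect was also higher in late cells for Afp (1.63), Prom1 (2.32) and Cdkn2a (1.90), which fell at P1. The known targets of the inducers Fkbp5 (-0.02) and Socs3 (-0.80) did not pass, nor did G6pc (-0.01). When single arrays were left out, Afp lost its call (highest adjusted p 0.057), as did Cps1 (0.076). For acute-phase and complement genes the smaller effect went with a larger median rise in uninduced late cells. Against day 0, acute-phase medians in late and P1 cells were 4.02 and 1.13 without and 4.64 and 4.33 with induction. Those of complement were 3.36 and 0.78, and 4.78 and 4.56, and of the urea cycle -0.07 and 0.09, and 0.26 and 2.57. These medians, not tested between passages, are unbounded and cover fewer genes in late cells, which can favour the late ones.

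Lower in late than in P1 cells were the effects on acute-phase genes (13 of 28, median -1.18 and -0.92 without dim genes, quantile median -0.70, adjusted p = 2.2e-07, estimated-correlation adjusted p = 0.15) and cholesterol synthesis (15, or 16 adjusted over the list alone, of 20, median -1.29, adjusted p = 7.0e-12, estimated-correlation adjusted p = 0.15). The effects were also lower on the urea cycle and amino acid catabolism (10, or 11 adjusted over the list alone, of 18, median -1.98 and -2.01 without dim genes, adjusted p = 5.9e-08, estimated-correlation adjusted p = 0.15) and phase II enzymes (11 of 17, median -1.54 and -1.17 without dim genes, adjusted p = 1.7e-05, estimated-correlation adjusted p = 0.17). Fatty acid synthesis (7 of 14, median -1.20 and -0.81 without dim genes, adjusted p = 4.4e-05, estimated-correlation adjusted p = 0.15), the unfolded protein response (7 of 15, median -0.97, adjusted p = 4.8e-07, estimated-correlation adjusted p = 0.15) and complement and coagulation (7, or 9 adjusted over the list alone, of 25, median -1.83 and -0.92 without dim genes, adjusted p = 6.1e-04, estimated-correlation adjusted p = 0.43) followed. The same held for secreted proteins (median -0.85 and -0.75 without dim genes, quantile median -0.40, adjusted p = 0.0070, estimated-correlation adjusted p = 0.46), P450 and other phase I enzymes (median -1.08 and -0.64 without dim genes, normexp median -0.63, adjusted p = 0.0060, estimated-correlation adjusted p = 0.39) and gluconeogenesis (median -1.05 and -0.90 without dim genes, adjusted p = 0.0057, estimated-correlation adjusted p = 0.43). It held for bile acids (median -1.14 and -1.24 without dim genes, normexp median -0.46, adjusted p = 0.0049, estimated-correlation adjusted p = 0.19) and fatty acid oxidation (median -0.30 and -0.20 without dim genes, quantile median -0.19, adjusted p = 0.0098, estimated-correlation adjusted p = 0.40) too. NRF2 targets (median -0.46 and -0.42 without dim genes, normexp median -0.29, adjusted p = 0.046, estimated-correlation adjusted p = 0.39) were called lower, but not with the slide as a block (0.10), under normexp (0.12), with the mean of all probes (0.10) or without several single arrays (highest adjusted p 0.072). Higher were the effects on progenitor and biliary (median 0.79 and 0.75 without dim genes, adjusted p = 0.014, estimated-correlation adjusted p = 0.43) and fetal and imprinted genes (median 0.86 and 0.87 without dim genes, adjusted p = 0.019, estimated-correlation adjusted p = 0.17). They were also higher on cell cycle (median 0.42, normexp median 0.20, adjusted p = 0.0017, estimated-correlation adjusted p = 0.46), YAP/TEAD (median 0.62 and 0.69 without dim genes, adjusted p = 0.021, estimated-correlation adjusted p = 0.43) and Wnt feedback genes (median 0.48 and 0.18 without dim genes, normexp median 0.10, quantile median 0.78, adjusted p = 0.010, estimated-correlation adjusted p = 0.15). Without single arrays the fetal, progenitor and YAP/TEAD lists lost their calls (highest adjusted p 0.084, 0.058 and 0.072), the fetal list also with the slide as a block (0.065). Medians then ranged from -2.91 to -1.10 for complement, -1.48 to -0.50 for secreted protein, -1.86 to -0.66 for gluconeogenesis and 0.18 to 0.89 for Wnt feedback genes, the lowest of the first 3 without late induced replicate 3. The glucocorticoid-responsive list was not called (1 of 18 lower, median 0.03 and 0.08 without dim genes, adjusted p = 0.97). The TGF-beta, immediate early, interferon, Kupffer cell and lymphocyte lists, not called, had a median, mean and test that differed in sign. Among cholesterol genes, Sqle, Insig1 and Lss rose with induction at P1 (2.01, 2.06 and 2.05), while in late cells Sqle stood at 0.46 and did not pass.

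Over 22353 genes the effect was higher in late cells for 1057 and lower for 1164. These counts were 1324 and 1405 with the slide as a block, where the medians were -1.45 for acute-phase genes and -1.29 for cholesterol synthesis. A common part remained among the 19579 genes tested at both passages. Of 1660 genes up at P1 and 539 up in late cells 355 were shared (45.7 by chance), Socs3, Fkbp5 and Serpina3n among them. Of 1735 and 588 that were down, 436 were shared (52.1 by chance; 261 under normexp), with Cyr61, Thbs1 and Ankrd1 among them. The induction changes at P1 and in late cells correlated with r = 0.64 (Spearman rho 0.56) across all of the genes tested at both. Of 4511 common genes that fell on conversion, 278 rose with late induction (6.16%, 124 by chance) and 62 fell (135 by chance). Of 5087 that rose on conversion, 423 fell (8.32%, 153 by chance). Genes already dim in late CLiPs could hardly fall here either, so none of these chance counts is a fair expectation. Passage and array set cannot be told apart, since the late arrays were processed with another software version on another scanner.

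**Figure D4:**
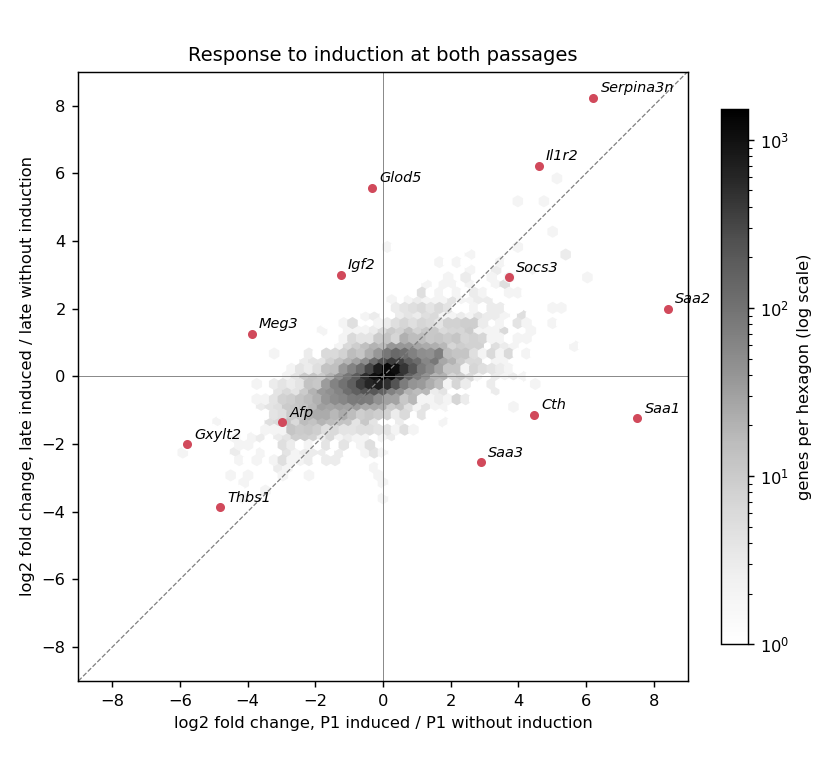
Log2 fold change with induction at P1 and in late CLiPs for 19579 genes (r = 0.64).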

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

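The tests of signal range, of single late arrays and of stellate cell genes and the regroupings of arrays were chosen after the results were seen, while the tests of scaling, of spread between late arrays and of slide 7 were set before. What drew attention here was the difference of the induction effects between late and P1 cells, which passed a test of the difference itself for 1057 genes with a higher and 1164 with a lower effect in late cells, where higher includes a smaller fall. Passage and array set cannot be told apart, so each value below holds for both.

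Genes with a lower effect in late cells were Saa1 (-8.76), Saa2 (-6.41), Saa3 (-5.44), Cpb2 (-5.99), Cth (-5.59), Slc27a5 (-5.23), Tat (-2.79) and Cps1 (-1.95, not well above background on some late arrays). Abcb11 (-3.88) was not well above background in uninduced cells of either passage, so its value is not a measured difference, and it lost its call when single arrays were left out (highest adjusted p 0.076). Genes with a higher effect were Glod5 (5.89), Meg3 (5.13), Tlr3 (4.42), Igf2 (4.25), Gxylt2 (3.77), Tspan8 (3.76), Prom1 (2.32), Cdkn2a (1.90) and Afp (1.63). Median effects were lower for the lists of urea cycle and amino acid catabolism (-1.98), complement and coagulation (-1.83, -2.91 without late induced replicate 3), phase II enzymes (-1.54), cholesterol synthesis (-1.29), fatty acid synthesis (-1.20) and acute-phase genes (-1.18). They were also lower for bile acids (-1.14), P450 and other phase I enzymes (-1.08), gluconeogenesis (-1.05), the unfolded protein response (-0.97), secreted proteins (-0.85) and fatty acid oxidation (-0.30). The call of NRF2 targets (-0.46) was lost in 13 of 20 settings. Median effects were higher for fetal and imprinted (0.86), progenitor and biliary (0.79), YAP/TEAD (0.62), Wnt feedback (0.48, 0.10 under normexp) and cell cycle genes (0.42). Of these, the fetal, progenitor and YAP/TEAD lists lost their calls without single arrays. With an estimated correlation none of the 18 called lists passed (lowest adjusted p 0.15).

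Fewer genes passed for induction in late cells (1278) than at P1 (3857). A compressed signal range on the late arrays would shrink other changes too, but the SD over genes of the 8-day change without induction was larger in late cells (ratio 1.23, 1.19 to 1.31 without single arrays). The 8-day change may itself differ with passage, so this ratio does not exclude compression. A larger spread between the late arrays would leave the true size of the effects alone, but with sampling variance taken out the SD of the induction change was 0.640 times that at P1 (0.624 to 0.658 without single arrays). No single late array accounted for it, since the count without any one of them was 1075 to 1280, at most 1.002 times the count with all. Against day 0, 4421 genes passed in induced late and 4736 in induced P1 cells, and 3100 and 2297 in uninduced ones. The fewer induction calls in late cells thus went with more changes without induction. What stays open is whether passage or another difference between the array sets made the effect smaller.

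Cholesterol synthesis genes rose with induction at P1 (15 of 20) and not in late cells (0 of 20). Array scaling does not account for this: relative to the median of all genes, the median difference of the list was -1.25 at the nearest to 0 under quantile normalization and normexp. Slide 7 does not either, with -1.36 when its array was left out. With the slide as a block the list median was -1.29. Passage may be the cause, but it cannot be told apart from the array set.

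Endothelial and macrophage genes fell between fresh hepatocytes and P1 day-0 CLiPs. Array scaling is argued against, since relative to the median of all genes the smaller of both list changes was -2.12 under the other scalings. Other liver cells in the fresh preparation that culture did not keep could give such a fall, and stellate cell genes, tested for this, moved both ways (median -0.0174), so the test decides nothing. A fall of these genes within the cultured cells stays open too and was not tested.

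The arrays of each comparison of 3 with 3 were also regrouped in all 10 possible ways. In each of the 8 comparisons only 1 grouping, the real one, gave as many genes. The highest count of another grouping was 5 (late induced against day 0, 4421 in reality), then 1 (late induction, 1278 in reality) and 0 in the others (10437, 3857, 4736, 2297, 8066 and 3100 in reality). With 10 groupings a share under 0.05 cannot be reached. For the difference of the induction effects (2221 genes), 100 regroupings of the induction labels within each passage gave 12 at least as large, the real one included, with a highest count of 4127, and the other 11 were all those that kept the P1 labels whole. These set the full P1 effect against scrambled late arrays and give many genes by design, so this regrouping decides nothing about chance. Regrouping the passages within each treatment, with each passage's mean removed, gave 1 of 100, with a highest other count of 1052. Mixing arrays of both sets within a group can add spread and so lower the counts of the other groupings. The labels do not say whether the replicates are independent either. This regrouping thus excludes neither chance nor the array set.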

How the results depend on the processing

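The fits within single slides were chosen after the results were seen; all other alternatives were set before. No overlap or similarity result changed its direction. Which of the higher and lower counts was the larger turned under at least 1 setting in each comparison except induced against day-0 cells at P1 and in late cells, so the balance of the counts is not a result. Of 1200 results of named genes, 1179 kept direction and side of the threshold under quantile normalization and 1135 under normexp. This held for 1153 without a filter on dim probes, 1136 with the mean of all probes, 1168 with only the compared groups in the fit, 1198 with a trended and robust variance, and 1184 with the replicate block. The authors' values, the same signals shifted, gave 1199 of 1199 by construction, and the slide as a block 889 of 914. Within slide 4 it was 374 and within slide 5 337 of 412 each, where a group held 1 or 2 arrays and the spread came from all groups, with the slide as a random block (correlation 0.528) 285 of 286, and without single arrays 7565 of 7962. The one called result with the opposite sign was the difference of the induction effects for Bub1 under normexp, with a log2 value of -0.033 (adjusted p = 0.94; 1.29 before); the cause was not tested. Uncalled results changed sign 225 times. Of 292 list results 156 lost their call with an estimated correlation, 7 under quantile normalization and 5 under normexp. Of 156 medians of called lists 24 moved by over 1.5-fold under normexp, 7 under quantile normalization, 5 with the mean of all probes and 5 without a filter on dim probes. Where the numbers pair the samples, the replicate block changed no call beyond those given in the comparisons and no count by over 1.5-fold. For induced P1 arrays the pairing is unclear. Same-numbered pairs correlated with 0.188, -0.136 and 0.368 (day 0) and 0.388, 0.0527 and 0.381 (uninduced), but induced replicate 2 lay on another slide than its partners. Pairs of different numbers on one slide gave 0.296 and 0.109 (day 0) and 0.0759 and 0.0771 (uninduced). The fresh arrays share only a number with the others (-0.103 to 0.0168). For induced P1 and fresh arrays not every sample correlated best with its own number. With the block the counts moved to 5242 and 5212 for P1 day 0 against fresh, 2003 and 1863 for P1 induction, and 2579 and 2177 for induced P1 against day 0. They moved to 4197 and 3884 for induced P1 against fresh and 1201 and 1273 for the difference of the induction effects. The difference of the induction effects joins paired late arrays with P1 arrays whose pairing is unclear. In it, with the block, the NRF2 list (adjusted p = 0.098), Mcm5 (0.058) and Ier3 (0.075) did not pass, while Abcc2 (0.017), Krt19 (0.047) and the p53 list (0.041) did. For induced P1 against day 0 the fatty acid synthesis list did not (0.067). The median of all genes moved by over 0.1 in 3 cases: by 0.14 under quantile normalization and -0.16 under normexp for P1 day 0 against fresh, and by -0.12 under normexp for induced P1 against fresh cells.

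Without a minimum fold change, which passes more genes by construction, the higher and lower counts were 8138 and 8170 for P1 day 0 against fresh, 5174 and 4065 for P1 induction, 5631 and 5019 for induced P1 against day 0, and 3431 and 4050 for uninduced P1 against day 0. They were 7640 and 7091 for induced P1 against fresh and 2231 and 1710 for late induction. In late cells against day 0 they were 6015 and 5442 with and 4410 and 4954 without induction, and 2019 and 2215 for the difference of the induction effects. With only genes well above background on every array, which tests fewer genes by construction, they were 2746 higher for P1 day 0 against fresh and 1302 and 635 for P1 induction. They were 1536 and 1068 for induced and 496 and 565 for uninduced P1 against day 0, 1893 higher for induced P1 against fresh, 402 higher for late induction and 379 and 691 for the difference. Then 862 genes that fell on conversion rose with P1 induction and 162 with late induction, and 186 higher and 116 lower genes were shared. Under normexp the counts were 1169 lower for P1 induction, 752 higher for uninduced P1 against day 0 and 2576 higher for induced P1 against fresh. They were 392 lower for late induction, 1129 higher for uninduced late cells against day 0 and 261 lower genes shared; the cause was not tested. Within slide 5, with 1 array per group by construction and the spread from other groups, so no separate test, 584 genes were higher and 501 lower in uninduced P1 cells against day 0. Without single arrays no count changed by over 1.5-fold. P1 day 0 against fresh gave 5157 to 5268 higher and 5123 to 5294 lower genes, P1 induction 1907 to 2061 higher and 1727 to 1892 lower. Induced P1 cells against day 0 gave 2387 to 2599 higher and 2074 to 2184 lower, uninduced ones 1083 to 1339 higher and 881 to 1056 lower, and induced ones against fresh 4118 to 4248 higher and 3703 to 3993 lower. Late induction gave 509 to 638 higher and 548 to 642 lower. Late cells against day 0 gave 2194 to 2420 higher and 1948 to 2097 lower with and 1573 to 1798 higher and 1263 to 1435 lower without induction. The difference of the induction effects gave 888 to 1195 higher and 967 to 1356 lower. Genes that fell on conversion and rose with induction were 1246 to 1337 at P1 and 222 to 283 in late cells, and shared genes 301 to 349 higher and 360 to 430 lower. The gain in correlation with fresh cells was 0.0948 to 0.103. Signal over background limits what can be said of dim genes: of 10437 genes called between P1 day 0 and fresh cells, 2722 were not well above background in a group, so their size is known only as a minimum. The number of arrays limits the precision.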

Other observations

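The genes in this part were chosen after their values were seen. Among hepatocyte genes that rose in late CLiPs over 8 days without inducers, Acox2 of bile acid synthesis rose with a log2 fold change of 5.38, the plasma protein gene Apoh with 4.51, and the liver regulator genes Onecut1 and Prox1 with 2.93 and 2.36. Vtn was at least 65.0-fold higher. Lcn2, a member of both the acute-phase and the progenitor list, rose with 3.31 and the epithelial transcription factor gene Ehf with 3.27, and in P1 CLiPs over the same time with 1.24 and 2.07. Krt19 (-1.04) and Cd44 (0.14) did not pass in late cells. The imprinted gene H19 rose in late (6.32, well above background on 2 of 3 day-0 arrays) and in P1 CLiPs (1.86), where the call was lost without a filter on dim probes and when single arrays were left out (highest adjusted p 0.12). The difference between the passages was not tested for these 8-day changes.

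As a check of the samples, the X-linked gene Xist was well above background by at least 1 probe on 21 of 21 arrays, and the Y-linked genes Ddx3y on 0, Eif2s3y on 1 and Uty on 1. The Y-linked gene Kdm5d was above it on 21, and the cause was not tested.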
